A study of Mus musculus with 4 samples.

How the data were processed

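Gene expression was measured by RNA-seq in group 1 innate lymphoid cells (ILC1s) taken from the livers of adult mice at homeostasis, aged 5 to 8 weeks per the labels. ILC1s are tissue-resident lymphocytes that resemble natural killer (NK) cells, produce interferon-gamma and carry cytotoxic granules. The 4 libraries fell into 2 groups by the genotype given in the labels: Cd200r knockout (replicates 1 and 2) and WT (replicates 1 and 3). The labels do not say whether replicates came from separate mice or from pools, so p-values measure the spread between these libraries, which may be technical in part. The antibodies and gates used to isolate the cells are not given in the sources used here.

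Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was reverse transcribed and amplified with a full-length single-cell kit, and libraries were built with a transposase-based kit. Such a kit does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, the tools were fastp, HISAT2, HTSeq, DESeq2 and R 3.2.0, and the genome build was mm10. The notes give them no role or order. The deposited table holds FPKM (fragments per kilobase of gene, scaled to the fragments counted in the library) for 18804 genes, of which 14800 are annotated there as protein-coding and 4004 as non-coding. A gene at 0 in all 4 libraries was found 649 times. No scaling between libraries is stated. Gene symbols and Entrez identifiers were used as deposited, and 18290 identifiers (97.3%) matched the RefSeq table of GRCm38.p6, the assembly of mm10, from which coordinates were taken.

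The table holds no read counts, so no count-based test was run. The summed FPKM per library ranged from 511415 to 523717. Depth was inferred from low values: among 472 genes with a single exon in GENCODE release M21, the smallest repeated step between values gives the worth of 1 read. This gave 41164777 and 39493877 counted reads for knockout replicates 1 and 2, and 39349312 and 38972600 for WT replicates 1 and 3. Between 70.1% and 72.1% of the low single-exon values per library then lay within 0.05 of a whole read. The most frequent ratio of low values between each pair of libraries equalled the ratio of the inferred depths. Both rest on the repeated step of low values in each library, so their equality is no separate check. At these depths, 1 FPKM corresponds to about 39.0 to 41.2 reads per kilobase. Read sums recovered for single-exon genes differed between replicates by 14.8 times (knockout, 183 genes) and 15.0 times (WT, 185 genes) the chi-square per degree of freedom of pure counting noise. Amplification alone can exceed counting noise, so this does not tell whether replicates came from separate mice. All 4 were treated as separate libraries.

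Values were analysed as log2(FPKM + 1) for the 9476 genes with a mean of at least 1 FPKM over the 4 libraries. The groups were compared with a two-sided limma 3.58.1 linear model with a mean-variance trend in R 4.3.3, with no covariate. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Log2 fold changes are knockout minus WT on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with the standard error (SE). Folds are ratios of group mean FPKM, and FPKM is given as mean ± SD of 2 libraries. An exact permutation test of 2 against 2 cannot give a p below 0.333.

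A total of 33 gene lists covering effector, receptor, signalling, metabolic and RNA quality programmes and markers of other liver cell types were written before the data were examined. The 30 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Beside each list, members past the gene test are counted, adjusted over all genes and adjusted over the list alone. Named genes followed a rule also fixed beforehand. They are Cd200r1 and its measured paralogs, the 10 largest rises and 10 largest falls among genes past the test with a mean of at least 5 FPKM and no overlap between groups, up to 4 members with the smallest p in each described list, and Gzma, Gzmb, Gzmc, Prf1, Fasl, Tnfsf10 and Ifng. Symbols of Gm and a number, symbols ending in Rik and pseudogenes were left out of the 20 largest changes. A gene named outside this rule is said to be so, and some genes that the rule names are not reported here. Gene ontology (GO) terms of 10 to 500 genes, as annotated in the deposited table, were tested for over-representation with a one-sided hypergeometric test against the 9226 tested genes that have a term.

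The gene and list tests were first run on 20 simulated data sets of 9476 genes in 2 against 2 libraries. They recovered 73.5% of genes changed 2-fold and 97.6% of genes changed 4-fold, and 4.26% of calls fell on unchanged genes. The simulated values followed the variance model that limma fitted to these data, with equal variance in both groups. A share of wrong calls near the threshold of 0.05 was therefore built in, and these rates need not hold in the data. With the preset correlation, 100% of lists of 20 genes shifted by 0.4 (log2) were recovered and 0.2% of unshifted lists were called. The simulated genes varied independently of each other. In the data, the estimated correlation was 0.557 for the conventional NK list and 0.667 for the macrophage list. It was −0.0625 for cytotoxic effectors and 0.0217 for cell cycle genes. These estimates rest on 2 residual degrees of freedom, so a value near 0 does not show that the genes of a list vary independently. The 0.2% therefore cannot be carried over to the lists in the data. With a correlation estimated from the data, 0% of the shifted lists were recovered, so that alternative cannot call a shift of this size in a design of 4 libraries. The GO test recovered 100% of planted terms and called none in 20 random gene sets. The planted sets held far more genes of 1 term than random drawing gives, and the random sets drew genes independently. Genes called in the data can vary together, so these values do not give the error rate of the GO test there. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used to read the table, and matplotlib 3.10.9 to plot.

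Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter of at least 5 FPKM, rescaling to one common sum per library (TPM), quantile normalization, median log ratio scaling, leaving out each library, limma without the trend, an adjusted p of 0.1, protein-coding genes alone, and 2 other list tests (camera with an estimated correlation, and fry). Rescaling without the 5 haemoglobin and 13 mitochondrial mRNA genes was added after the data were seen. Members of multigene families with similar sequences (the Ly49 receptors encoded by Klra genes, the Cd200r paralogs, Hba-a1 and Hba-a2, Hspa1a and Hspa1b) can share reads, and their values are uncertain to that extent.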

Results

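Liver ILC1s from mice labelled as knockout for Cd200r, which encodes CD200R, an inhibitory receptor of the immunoglobulin superfamily, were compared with ILC1s from WT mice. The title of the series relates CD200R to the cytotoxicity of these cells, and this comparison asks how their transcripts differ between the genotypes. The data are FPKM values of 2 Cd200r knockout and 2 WT libraries. Inferred depth was similar in all 4, from 38972600 to 41164777 counted reads. All adjusted p-values for genes are from limma and those for gene lists from limma's camera, unless another test is named.

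The targeted gene was examined first. Cd200r1 (Entrez 57781, GRCm38 chromosome 16, 44765736 to 44794977) measured 110.7 and 103.7 FPKM in the knockout libraries and 161.5 and 173.3 FPKM in the WT libraries. It was 1.56-fold lower in knockout, with a log2 fold change of −0.64 (SE 0.09, adjusted p = 0.0045). The transcript was therefore reduced and not absent. Which exons the allele lacks is not given in the sources used here, and a value summed over the whole gene includes reads from any exons left in place. The neighbouring paralog Cd200r2 measured 309.3 ± 26.7 FPKM in knockout and 291.8 ± 22.9 in WT, and Cd200r4 76.9 ± 2.87 and 76.2 ± 0.782. Neither passed the test (adjusted p = 0.742 and 0.966). Cd200r3, with a mean of 0.921 FPKM, was below the filter. The adaptors and phosphatases listed with CD200R gave no member past the test other than Cd200r1 among 11 measured, and the list did not pass (adjusted p = 0.139), although it passed without knockout replicate 1 (mean −0.19, adjusted p = 0.0341, against a mean of −0.11 in all libraries and −0.02 without knockout replicate 2). Dok2, which encodes a docking protein bound by the receptor, had a log2 fold change of −0.13 (SE 0.09). Ptpn6 (−0.19, SE 0.08) and Inpp5d (−0.21, SE 0.15), both encoding phosphatases, also did not pass.

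Of 9476 genes tested, 316 differed between the groups, 227 higher and 89 lower in knockout. Among genes with a mean of at least 5 FPKM and no overlap between the groups, the largest rises were in Cma1, Spp1, C1qc, C1qb, Lgmn, Aif1, Klra4, C1qa, S1pr5 and Ms4a4a, with log2 fold changes from 3.53 down to 2.11. The 10 largest falls, from −2.44 to −1.09, included Ctse, Gzmc, Alas2, Cd24a, Wdfy1, Tmem254, AA467197, Hbb-bs and Mmp9. Ctse, which encodes the aspartic protease cathepsin E, was 5.77-fold lower, at 12.6 ± 0.253 FPKM in knockout and 72.8 ± 6.93 in WT (log2 fold change −2.44, SE 0.12, adjusted p = 1.29e-05). At least a 2-fold change with no overlap between the groups was found for 210 genes, 173 higher and 37 lower, and for 373 and 54 genes with pseudocounts of 0.1 and 5. The groups did not overlap in 46.0% of all genes, where chance gives 33.3%. The count of 316 depends on the filter and the variance model. Limma called 0 genes when all 18155 genes above 0 were tested, although 1898 had an unadjusted p under 0.05, and 70 genes without the mean-variance trend.

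**Figure D1:**
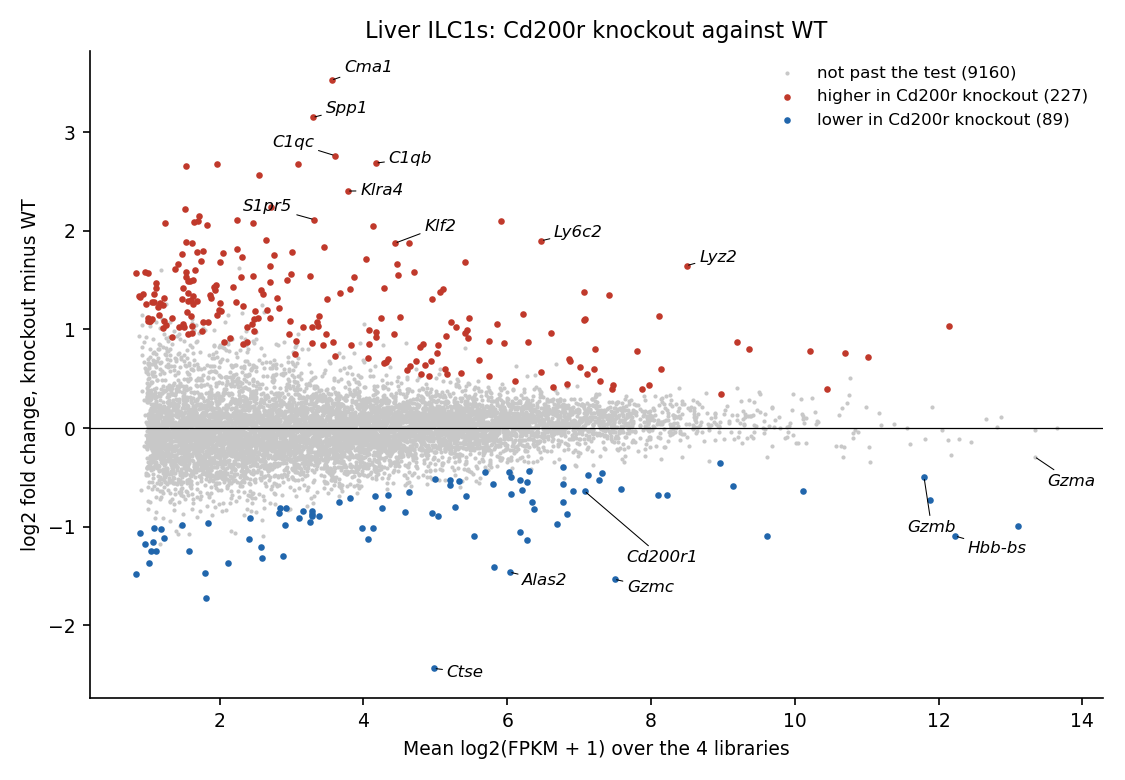
Log2 fold change (knockout minus WT, log2(FPKM + 1) scale) of each of 9476 genes against its mean log2(FPKM + 1) over 4 libraries. Red points are the 227 genes higher and blue points the 89 genes lower in knockout at an adjusted p under 0.05 (limma), and grey points did not pass; Cma1 (3.53) and Ctse (−2.44) are the extremes among the labelled genes.

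Some transcripts of cytotoxic granules were lower in the knockout. Gzmc, encoding granzyme C, was 2.90-fold lower, at 105.5 ± 15.4 FPKM in knockout and 305.7 ± 19.5 in WT (log2 fold change −1.53, SE 0.11, adjusted p = 1.0e-04). Gzmb, encoding granzyme B, was 1.41-fold lower, at 2996 ± 133 and 4236 ± 15.3 FPKM (−0.50, SE 0.08, adjusted p = 0.00558). Cst7, encoding the cathepsin inhibitor cystatin F, was 1.60-fold lower (−0.68, SE 0.10). Lamp1, a lysosomal membrane protein exposed at degranulation, was 1.49-fold higher (0.57, SE 0.11, adjusted p = 0.0218), but did not pass without knockout replicate 2 (0.45, adjusted p = 0.0691) or WT replicate 1 (0.48, adjusted p = 0.126). Of the 16 measured members of the cytotoxic effector list, 3 fell, 1 rose and 12 did not pass; adjusted over the list alone, 5 fell and 1 rose. The list as a whole was lower, with a mean log2 fold change of −0.16 and a median of −0.15 (adjusted p = 0.00914, but adjusted p = 0.374 with an estimated correlation and 0.0551 with fry). Gzma measured 9375 ± 875 FPKM in knockout and 11438 ± 79 in WT (−0.29, SE 0.09, adjusted p = 0.112), and passed without knockout replicate 2 (−0.39, adjusted p = 0.00789). Prf1, encoding perforin, had a log2 fold change of −0.13 (SE 0.12), Tnfsf10 of −0.33 (SE 0.18), Fasl of 0.01 (SE 0.08) and Ifng of −0.00 (SE 0.08), and none of these 4 passed. Without WT replicate 1 or 3, Gzmb kept its value (−0.50 in each case) but did not pass. Over the libraries left out, Gzmc ranged from −1.68 to −1.38 and Cst7 from −0.80 to −0.57. Of 13 alternatives, Gzmc passed in 12, Cst7 in 11, and Gzmb and Lamp1 in 9 each. With no filter none of these 4 passed, and without the mean-variance trend 48 of the named genes lost their call. With quantile normalization the log2 fold change of Gzmb was −0.30 (adjusted p = 0.0303) and that of Gzma was 0, since a gene of equal rank in all libraries is given equal values. In the same knockout libraries haemoglobin mRNA was lower and mitochondrial and macrophage mRNA higher (list means −0.72, 0.79 and 1.45 for erythroid, mitochondrial and macrophage genes).

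No gene of the machinery that moves and fuses granules passed. Among 21 measured genes, 0 passed over all genes and 1 fell adjusted over the list alone; limma's camera gave an adjusted p of 0.13. Its members with the smallest p were Sytl2 (−0.59, SE 0.14), Unc13d (−0.48, SE 0.18), Dock8 (−0.48, SE 0.20) and Ap3d1 (−0.45, SE 0.20), and none passed. All 4 passed without knockout replicate 1, with log2 fold changes of −0.62, −0.67, −0.80 and −0.74. Without knockout replicate 2 these were −0.56, −0.28, −0.16 and −0.15, so the falls of Unc13d, Dock8 and Ap3d1 rest largely on that library. Unc13d also had −0.28 without WT replicate 1. Sytl2 passed with the stricter filter (adjusted p = 0.0499).

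**Figure D2:**
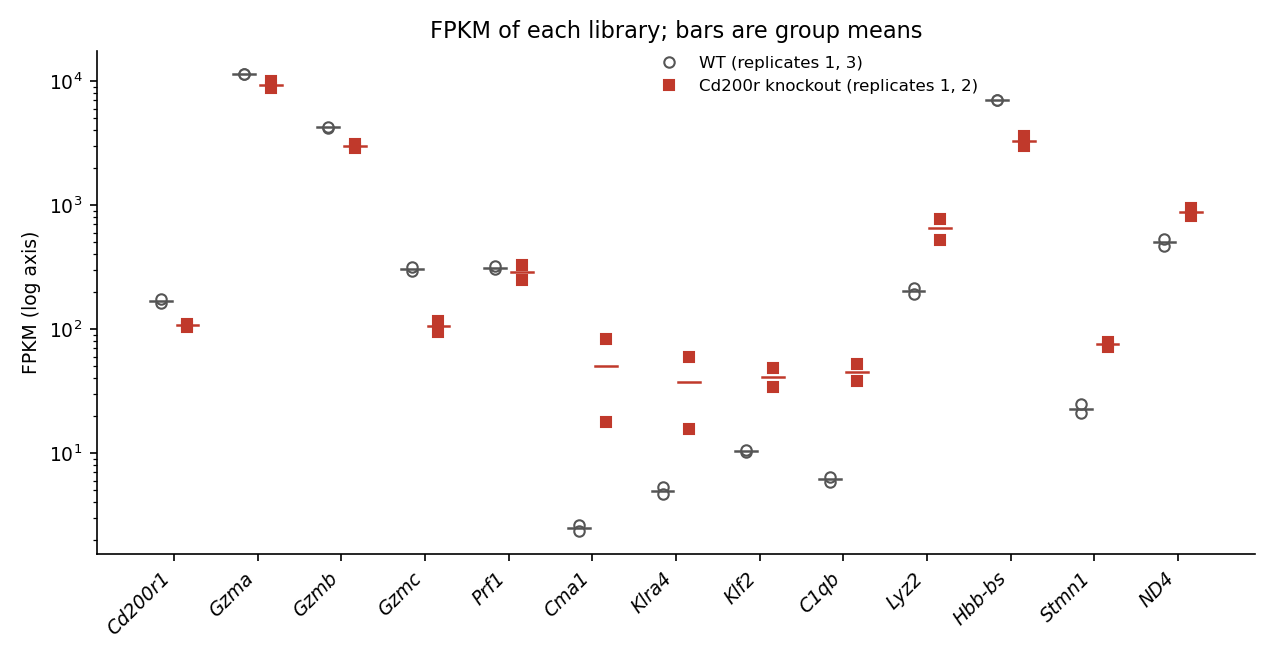
FPKM on a log axis of 13 genes in each library, WT as open circles and Cd200r knockout as filled squares, with a bar at each group's mean. Gzmb and Gzmc were lower in both knockout libraries, and Cma1 and Klra4 were higher in knockout replicate 2 (83.7 and 59.2 FPKM) than in replicate 1 (17.9 and 15.6 FPKM).

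Genes typical of conventional NK cells, the circulating relatives of ILC1s, were higher in knockout. Cma1, which encodes a mast cell chymase also transcribed in NK cells, was 20.5-fold higher by group means. S1pr5 (a receptor for egress from tissue, 5.95-fold), Klf2 (a transcription factor of recirculating lymphocytes, 3.98-fold) and Ly6c2 (3.85-fold) were also higher. Eomes, the transcription factor that marks conventional NK cells, rose from 0.836 ± 0.51 to 4.20 ± 1.71 FPKM (log2 fold change 1.49, SE 0.29, adjusted p = 0.0189). Of 18 measured members of the list, 11 rose, 0 fell and 7 did not pass, and 15 rose adjusted over the list alone. The mean log2 fold change was 1.37 and the median 1.56 (adjusted p = 1.87e-15, but adjusted p = 0.374 with an estimated correlation and 0.159 with fry). The rise was uneven between the knockout libraries. Without knockout replicate 2 the list mean was 0.91, and the log2 fold changes of Cma1, Klra4 and S1pr5 were 2.44, 1.47 and 1.35. Klrg1 and Klra7 then had 0.71 and 0.60, and Eomes had 1.15 and no longer passed (adjusted p = 0.088). Klra genes encode Ly49 receptors of similar sequence, which can share reads. Markers of macrophages (mean log2 fold change 1.45) rose and of erythroid cells (−0.72) fell in the same libraries.

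The ILC1 signature did not pass as a list. Of 18 measured members, Gpr183 (1.08, SE 0.17) and Tmem176b (0.45, SE 0.10) rose, 0 fell and 16 did not pass, while adjusted over the list alone 4 rose and 3 fell. The mean log2 fold change was 0.09 and the median 0.02 (adjusted p = 0.644). Rgs1 (0.51, SE 0.13) and Xcl1 (−0.34, SE 0.10) did not pass, although Rgs1 did without knockout replicate 2 (0.76) or with the stricter filter (adjusted p = 0.0499) and Xcl1 without knockout replicate 1 (−0.44). The direction of the list's test turned without knockout replicate 1 (mean 0.06). Tmem176b did not pass when knockout replicate 1, WT replicate 1 or WT replicate 3 was left out, with log2 fold changes of 0.37, 0.38 and 0.51, and passed in 6 of 13 alternatives. Quantile normalization (0.38, adjusted p = 0.105) and rescaling without haemoglobin and mitochondrial genes (0.42, adjusted p = 0.053) also ended its call.

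Single receptor genes passed while the receptor lists did not. Among 16 measured inhibitory receptors, 4 rose and 0 fell, namely Klra1 (1.38, SE 0.26), Cd300a (1.26, SE 0.25), Klrg1 (1.31, SE 0.29) and Klra7 (1.11, SE 0.24), of which Klrg1 and Klra7 are also on the conventional NK list. Adjusted over the list alone 6 rose and 3 fell, and the list did not pass (adjusted p = 0.547). Cd300a did not pass without knockout replicate 1 or WT replicate 1 (1.04 and 1.09), and Klra1 had 0.85 without knockout replicate 2. With quantile normalization Klrg1 (1.29, adjusted p = 0.0675) and Klra7 (1.03, adjusted p = 0.0684) did not pass. Among 27 activating receptors and signalling proteins, Sh2d1a (the adaptor SAP, 3.24-fold higher) and Crtam (3.0-fold higher) rose and Plcg2 (phospholipase C gamma 2, 1.49-fold lower) fell. The list did not pass (adjusted p = 0.384), and its mean of 0.04 differed in sign from its median of −0.04 and from the direction of the test. Adjusted over the list alone, 3 rose and 5 fell. Plcg2 did not pass without WT replicate 1 or 3 (−0.58 and −0.54).

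Among 13 cytokines and chemokines, Lta (lymphotoxin alpha, 2.55-fold higher) and Ccl1 (2.0-fold higher) rose, and Tnf (1.85-fold lower, log2 fold change −0.85, SE 0.15, adjusted p = 0.0105) fell. Adjusted over the list alone 4 rose and 3 fell, and the list did not pass (adjusted p = 0.644). Tnf did not pass without WT replicate 3 (−0.72), nor Ccl1 without knockout replicate 2 or WT replicate 3 (0.97 and 0.60) or with quantile normalization (0.99, adjusted p = 0.0601). Of 20 transcription factors of ILCs and NK cells, Klf2 and Eomes rose and 0 fell (list adjusted p = 0.139); adjusted over the list alone 5 rose. Lef1 (0.84, SE 0.21) and Irf8 (0.40, SE 0.11) did not pass, although both did without knockout replicate 1 (1.07 and 0.53). In the list of tissue residency and trafficking, 23 genes were measured, of which 4 rose, including S1pr5, Klf2 and Cx3cr1, and 3 fell, including S100a4 (−0.59) and Itgal (−0.48), named outside the rule. Adjusted over the list alone 8 rose and 5 fell, and the list did not pass (mean 0.36, adjusted p = 0.241), although it passed without WT replicate 3 (mean 0.38, adjusted p = 0.032).

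Proliferation genes were higher in knockout. Stmn1, which encodes the microtubule regulator stathmin, was 3.30-fold higher, at 75.4 ± 5.35 FPKM against 22.9 ± 2.83 (log2 fold change 1.68, SE 0.12, adjusted p = 1.11e-04). Rrm2 (a ribonucleotide reductase subunit), Aurkb (a mitotic kinase) and Birc5 (survivin) were 2.75-fold, 3.31-fold and 3.80-fold higher. All 27 measured cell cycle genes had a positive log2 fold change, 11 rose over all genes and 24 adjusted over the list alone. The mean log2 fold change was 0.81 (adjusted p = 1.02e-18, but adjusted p = 0.374 with an estimated correlation and 0.0299 with fry). Knockout replicates 1 and 2 were alike in this list, with mean log2(FPKM + 1) of 3.58 and 3.52 against 2.74 and 2.74 in WT replicates 1 and 3. In the same libraries macrophage (1.45) and mitochondrial (0.79) list means were higher and that of erythroid markers (−0.72) lower.

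All 13 mitochondrially encoded mRNAs had positive log2 fold changes and 11 rose, 13 adjusted over the list alone, with a mean of 0.79 (adjusted p = 1.02e-18, but adjusted p = 0.374 with an estimated correlation and 0.118 with fry). Examples are CYTB (2.03-fold), ND4 (1.75-fold), ND6 (1.75-fold) and ND1 (1.69-fold). These mRNAs made up 2.51% and 2.89% of summed FPKM in the knockout libraries and 1.30% and 1.64% in WT. Nuclear-encoded oxidative phosphorylation genes had a mean log2 fold change of 0.09, with 0 of 35 past the gene test over all genes or over the list alone, among them Uqcrc1 (0.24, SE 0.08), Sdhb (0.20, SE 0.09) and Ndufv2 (0.21, SE 0.11). The list passed (adjusted p = 0.0191, but adjusted p = 0.644 with an estimated correlation), and did not without knockout replicate 2, WT replicate 1 or WT replicate 3 (means of 0.04, 0.10 and 0.08), while its mean was 0.14 without knockout replicate 1. It depended on scaling, with a mean of 0.02 under quantile normalization (adjusted p = 0.600) and 0.06 when rescaled without haemoglobin and mitochondrial genes (adjusted p = 0.0538). It also did not pass without the trend (adjusted p = 0.099) or with fry (adjusted p = 0.312). Of 49 ribosomal protein genes, Rpl12 rose (0.42, SE 0.10) and 48 had a positive log2 fold change; 3 rose adjusted over the list alone. The mean was 0.18 (adjusted p = 3.14e-10, but adjusted p = 0.442 with an estimated correlation and 0.159 with fry). Rpl35 (0.33), Rps19 (0.33) and Rps14 (0.29) did not pass, although Rpl35 and Rps14 did without knockout replicate 1 (0.37 and 0.35). Rpl12 did not pass without knockout replicate 1, WT replicate 1 or WT replicate 3 (0.38, 0.49 and 0.35), and passed in 4 of 13 alternatives. It also lost its call with a pseudocount of 0.1 (adjusted p = 0.0502), TPM (0.0584), quantile normalization (0.107) and rescaling without haemoglobin and mitochondrial genes (0.0612).

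Interferon-stimulated and immediate-early genes changed in part. Ifi27l2a (2.26-fold), Usp18 (1.66-fold) and Oas1a (1.62-fold) rose among 26 interferon-stimulated genes, 0 fell and Oas3 (−0.71, SE 0.20) did not pass; adjusted over the list alone 4 rose and 2 fell (list adjusted p = 0.134, but 0.0299 with fry). Usp18 did not pass without WT replicate 1 (0.61), nor Oas1a without WT replicate 1 or 3 (0.73 and 0.60). Of 23 immediate-early and stress genes, 5 rose and 3 fell, and adjusted over the list alone 7 rose and 3 fell (list adjusted p = 0.182). Atf3 (16.6-fold) and Nr4a1 (4.14-fold), both stimulus-induced transcription factors, rose, whereas Hspa1a (a heat shock protein, 1.84-fold lower) and Jun (1.60-fold lower) fell. Atf3 was near the floor in WT, at 0.536 ± 0.0786 FPKM, against 8.92 ± 2.02 in knockout. Its log2 fold change was 2.68 (SE 0.23) and ranged from 1.32 to 3.81 over the alternatives. The list passed without knockout replicate 2 (mean 0.23, adjusted p = 0.0339).

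**Figure D3:**
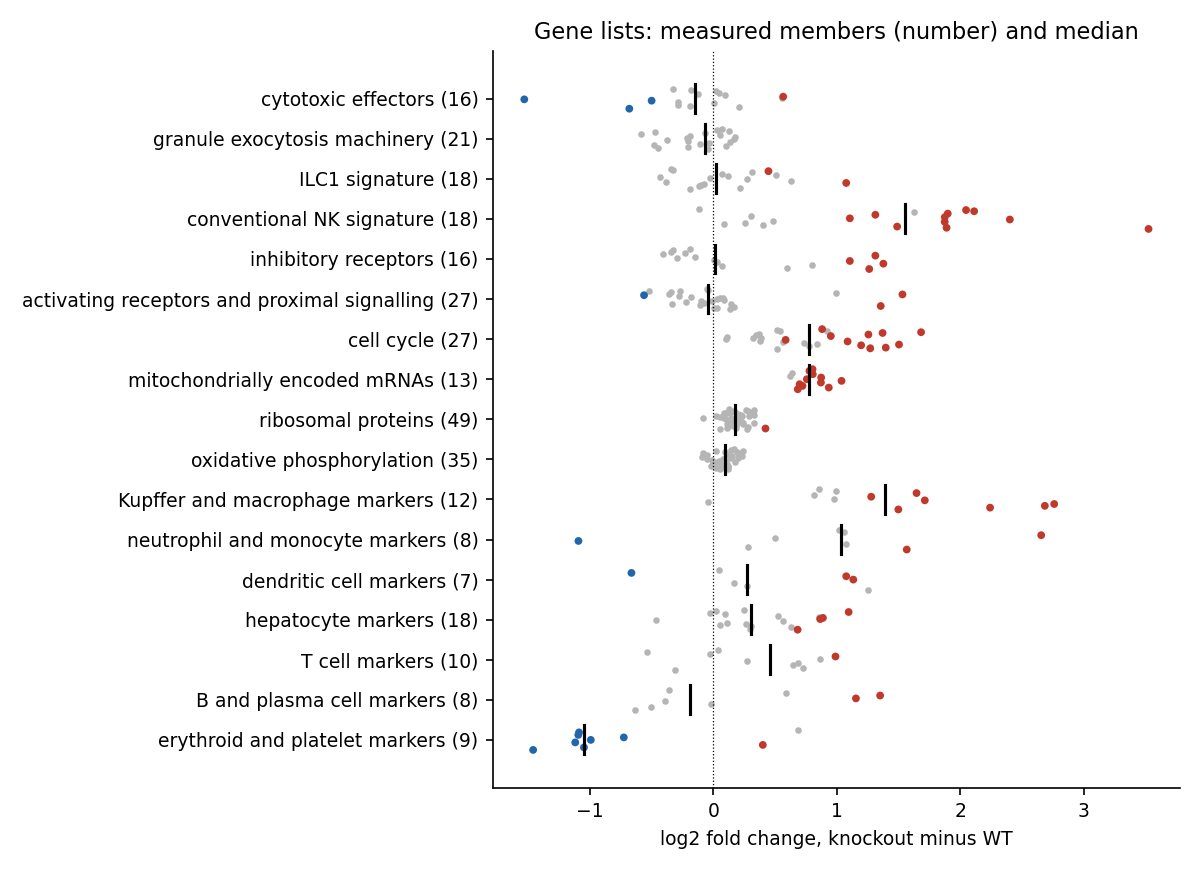
Log2 fold change (knockout minus WT) of every measured member of 17 gene lists, with the number measured in parentheses; red and blue points passed the gene test (adjusted p under 0.05, limma) as higher or lower, grey points did not, and the black bar is the list's median. Medians were −0.15 for cytotoxic effectors, 0.02 for the ILC1 signature, 1.56 for the conventional NK signature, 1.39 for macrophage markers and −1.05 for erythroid markers.

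Markers of other cell types also differed between the groups. Macrophage markers were higher in knockout: C1qb (7.41-fold), C1qc (8.68-fold) and C1qa (6.50-fold), which encode the chains of complement C1q, and Lyz2 (lysozyme, 648.9 ± 173 FPKM against 203.1 ± 14.4). Of 12 measured markers 7 rose and 0 fell, 10 rose adjusted over the list alone, and the mean was 1.45 (adjusted p = 9.56e-15, but adjusted p = 0.374 with an estimated correlation and 0.135 with fry). Erythroid markers were lower, led by Alas2 (haem synthesis, 2.83-fold), Hbb-bs (2.13-fold), Hbb-bt (2.13-fold) and Bpgm (2.09-fold). Of 9 measured erythroid and platelet markers 7 fell and Car2, named outside the rule, rose, with the same counts adjusted over the list alone. The mean was −0.72 (adjusted p = 2.89e-09, but adjusted p = 0.374 with an estimated correlation and 0.0951 with fry). Haemoglobin mRNAs made up 2.42% and 2.66% of summed FPKM in knockout and 4.78% and 5.15% in WT.

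Hepatocyte markers had a mean log2 fold change of 0.39, with 4 of 18 higher (Fgb, Serpina3k, Fga and Ahsg) and 0 lower, or 8 and 1 adjusted over the list alone (adjusted p = 2.41e-05, but adjusted p = 0.546 with an estimated correlation and 0.304 with fry). Without WT replicate 1 that mean was 0.21. Ahsg (0.68) did not pass without knockout replicate 2 (0.53, adjusted p = 0.145), without WT replicate 1 (0.53, adjusted p = 0.225) or with quantile normalization (0.66, adjusted p = 0.0813), nor Fga (0.87) without WT replicate 3 (0.81, adjusted p = 0.0785). Among 8 neutrophil and monocyte markers, Ngp and Camp rose from 0.154 and 0.0428 FPKM to 6.93 and 2.28 FPKM, and Mmp9 fell 2.16-fold (list mean 0.88, adjusted p = 0.00144, but adjusted p = 0.374 with an estimated correlation and 0.185 with fry). Adjusted over that list alone 6 rose and 1 fell, Cd14 (1.08, SE 0.30) did not pass over all genes but did without knockout replicate 1 (1.56) or WT replicate 3 (1.27), and Camp (1.57) did not pass without knockout replicate 2 (1.06), with quantile normalization (1.49, adjusted p = 0.0524) or with a pseudocount of 5 (0.51, adjusted p = 0.0583). Among 7 dendritic cell markers, H2-Eb1 (2.15-fold) and Cd74 (2.20-fold), of the MHC class II pathway, rose and Itgax (1.60-fold lower) fell, or 4 and 1 adjusted over the list alone (list mean 0.47, adjusted p = 0.0158, but adjusted p = 0.374 with an estimated correlation and 0.0193 with fry). With no filter that mean was 0.23 and the list did not pass (adjusted p = 0.438). Batf3 (1.26, SE 0.35) did not pass but did without knockout replicate 1 (1.79) or WT replicate 1 (1.55), and Itgax did not without WT replicate 1 (−0.57). Among 10 T cell markers Cd6 rose (2.29-fold) and Cd3e (0.69, SE 0.16), Cd3d (0.65, SE 0.17) and Cd28 (0.72, SE 0.21) did not pass; 5 rose adjusted over the list alone (list adjusted p = 0.0224, but adjusted p = 0.374 with an estimated correlation, 0.135 with fry and 0.059 with no filter). Cd6 (0.98) did not pass without WT replicate 1 (0.83, adjusted p = 0.168), whereas Cd3e and Cd3d passed without knockout replicate 1 (0.76 and 0.97), without WT replicate 1 (0.86 and 0.72) and with the stricter filter (0.69 and 0.65), and Cd28 without knockout replicate 1 (0.97). Without knockout replicate 2 Cd3e, Cd3d and Cd28 had 0.62, 0.33 and 0.48, and without WT replicate 3 they had 0.51, 0.58 and 0.63, and did not pass in either case. Among 8 B and plasma cell markers the MHC class II genes H2-Ab1 (2.54-fold) and H2-Aa (2.26-fold) rose, while Cd79a (−0.51, SE 0.20) did not pass except without WT replicate 1 (−0.78). That list did not pass (adjusted p = 0.622), except with the stricter filter (mean 0.52, adjusted p = 0.0333), its test and mean (0.15) differed in sign from its median (−0.19), and adjusted over the list alone 2 rose and 1 fell. Endothelial, stellate, and ILC2 and ILC3 markers had 3, 1 and 4 measured members and were not tested.

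The libraries separated by genotype along the first principal component, which held 61.0% of the variance. The second component (22.1%) set knockout replicate 1 (16.9) apart from knockout replicate 2 (−11.7), with WT replicates 1 and 3 together at −2.61 and −2.59. Of the 316 genes called, 278, 208, 211 and 229 were also called without knockout replicate 1, knockout replicate 2, WT replicate 1 and WT replicate 3. The total without knockout replicate 1 was 574 genes, 351 higher and 223 lower, and without WT replicate 1 the number of lower genes was 56.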

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

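Rescaling without haemoglobin and mitochondrial genes was chosen after the data were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because the groups share only replicate number 1. The count-based alternative was not run, since the table holds no counts, and genes under 5 FPKM have no value under the stricter filter. The 316 genes became 0 (0 higher, 0 lower) with no filter, 70 (57 higher, 13 lower) without the trend and 481 (150 lower) at an adjusted p of 0.1, and the genes higher became 151 with the stricter filter, where 205 of 205 called genes still tested were kept. Over the libraries left out, the count ranged from 256 to 574, genes higher from 170 to 351 and genes lower from 56 to 223. All 316 genes kept their sign under each scaling and each library left out. Where the groups do not overlap, leaving out 1 library cannot change the sign, so for such genes that part is no test. Genes changed 2-fold without overlap numbered 373 with a pseudocount of 0.1, 54 with 5, and 88 with the stricter filter. Cd200r1 no longer passed with no filter (−0.64, adjusted p = 0.302) or without the trend (−0.64, adjusted p = 0.108). It passed in 11 of 13 alternatives, with values from −0.70 to −0.59. The cytotoxic effector list kept its direction in 15 alternatives (−0.21 to −0.13) and passed in 11. It did not pass with no filter (−0.13, adjusted p = 0.108), without the trend (−0.16, adjusted p = 0.12), with an estimated correlation (−0.16, adjusted p = 0.374) or with fry (−0.16, adjusted p = 0.0551). Of 30 lists, 12 passed, against 0 with an estimated correlation, which recovered no simulated shift of 0.4 (log2) in independent genes. Larger shifts, such as the means of the conventional NK (1.37), macrophage (1.45) and cell cycle (0.81) lists, were not simulated. Whether that test could call them is therefore not known. With fry 3 passed, of which cell cycle and dendritic cell lists were among the 12 and interferon-stimulated genes were not, and the other 10 lost their call. Some values near 0 changed sign, none of them past the test before or after. Under the stricter filter the test direction turned for inhibitory receptors (mean 0.19) and for cytokines (−0.025). Fasl had −0.000705 with TPM, −0.0887 with quantile normalization and −0.0190 without haemoglobin and mitochondrial genes. Cd200r2 had −0.00202 and Cd200r4 −0.0399 with quantile normalization, and Cd200r4 −0.0131 without haemoglobin and mitochondrial genes. Over the libraries left out, values ranged from −0.0524 to 0.0667 for Fasl, −0.00421 to 0.172 for Cd200r2, −0.0248 to 0.0504 for Cd200r4, −0.318 to 0.0668 for Prf1, −0.439 to 0.0126 for Inpp5d and −0.0504 to 0.0418 for Ifng. The ILC1 list mean stayed positive (0.0556 to 0.129), and only its test direction turned, without knockout replicate 1 (0.0556). The cause was not tested, except that the no-filter setting adds 8679 low genes and a left-out library leaves a lone sample assumed to vary like the other group. Inferred depth limits genes near 1 FPKM to about 39 to 41 reads per kilobase.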

Other observations

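The GO terms and the genes named here outside the rule were chosen after the data were seen, as were all the tests of explanations in this part. Among the 222 genes higher in knockout that have a GO term, 7 of the 15 tested genes of chemokine activity were found, where 0.361 were expected by chance (adjusted p = 5.89e-06, hypergeometric test over 2538 terms). They were Ccl1, Ccl2, Ccl6, Ccl9, Ccl24, Cxcl2 and Cxcl16, all encoding chemokines. Macrophage markers rose in the same libraries (list mean 1.45), so neither these genes nor the MHC class II genes below are assigned to ILC1s. Ccl2 rose from 0.536 and 0.605 FPKM in WT to 4.46 and 7.29 FPKM in knockout. Presentation of exogenous peptide by MHC class II held 7 of 17 (adjusted p = 1.20e-05), among them Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1 (1.84, SE 0.18). Blood coagulation held 6 of 38 (adjusted p = 0.0106), including the fibrinogen genes Fga, Fgb and Fgg, which hepatocytes express, and mitotic cytokinesis held 8 of 45 (adjusted p = 7.40e-04).

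Among the 83 genes lower in knockout that have a term, serine-type endopeptidase activity, as annotated in the table, held 9 of 56, where 0.504 were expected (adjusted p = 3.38e-06). Only Gzmb and Gzmc of these 9 encode granzymes. Cela2a, Ctrb1 and Try4 encode digestive enzymes of the exocrine pancreas; Cela2a measured 0.711 and 1.18 FPKM in knockout and 3.66 and 7.70 FPKM in WT. The other 4 were Ctse, Mmp9, Htra1 and Htra3. Ctse encodes an aspartic protease, so the annotated term is not limited to genes of serine proteases. Of the 7 tested lists not described above, 0 passed with limma's camera. Their adjusted p-values were 0.632 (cytokine receptors and JAK-STAT), 0.433 (glycolysis), 0.644 (fatty acid and cholesterol metabolism), 0.451 (unfolded protein response), 0.644 (apoptosis), 0.644 (NF-kB) and 0.433 (MAPK and PI3K-mTOR). Single members that rose in them were Il18r1 (1.03) and Il18rap (0.76), the chains of the interleukin-18 receptor, Fabp5 (1.24), Pmaip1 (1.42), Tnfaip3 (1.06), Nfkbia (0.43) and Dusp5 (1.12).

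The first pattern weighed is the rise of conventional NK transcripts, for which NK cells within the sorted population are a candidate source. A lower share of ILC1s that raised every other cell type alike would raise erythroid markers too, but these fell (mean −0.72, standard error over members 0.247). That error takes the members as independent, while their estimated correlation was 0.406. Macrophage (1.45), neutrophil and monocyte (0.88), dendritic (0.47), hepatocyte (0.39) and T cell (0.33) list means rose, and the B cell list did not pass. A lower share of ILC1s that raised only some cell types therefore stays open. One added population of fixed profile would bring its genes at 1 ratio between the knockout libraries, but the excess over the WT mean in replicate 2 relative to replicate 1 ran from 1.59 to 5.27 over the 11 members that passed, and from 1.28 to 11.2 over the 15 above WT in both (Cochran's Q 59.8 over 10 degrees of freedom for the 11). The log2 ratio was lowest for Klf2 (0.67, SE 0.27) and Ly6c2 (0.74, SE 0.19), with Eomes (1.08, SE 0.59) and Cx3cr1 (1.34, SE 0.52) between these and the other 7, and its spread lay at the 54.16th percentile of 10000 random sets of other genes higher in knockout. Whether added cells had 1 profile was not measured, so conventional NK cells as the source of all or part of the rise, and a change within the knockout ILC1s, stay open; 16 of the 18 list members were at 1 FPKM or more in WT, and the gate is not given.

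The second pattern is the rise of macrophage transcripts, tested on the 7 list members that passed. Their excess ratios were alike, from 1.36 to 1.89, with no more spread than replicate noise gives (Cochran's Q 2.27 over 6 degrees of freedom, where the cell cycle genes that passed also showed no excess, with 14.5 over 10) and a spread at the 0.11th percentile of 10000 random sets of 7 other genes higher in knockout. The gene test favours genes alike in both knockout libraries, so choosing these 7 by it could narrow their spread beforehand. Genes in the random sets had passed that test too. The SD of the log2 ratio was 0.177 over the 7 and 1.47 over the 11 members above the WT mean in both knockout libraries. For the 7, RNA of 1 added source in the knockout samples, such as macrophages or their free RNA, stays open. The most abundant were Lyz2 (648.9 FPKM) and C1qb (45.4 FPKM), and 11 of the 12 markers were at 1 FPKM or more in WT. Mature Kupffer cells as the only source are argued against, because Clec4f, Vsig4 and Cd5l had a median log2 fold change of 0.85 (largest SE 0.421) against at least 2.24 for the C1q genes (0.16 against 2.07 without knockout replicate 2, 1.55 against 2.42 without knockout replicate 1, and 0.57 against 2.01 without WT replicate 1). Over the 11 members above the WT mean in both knockout libraries the ratio spanned 1.05 to 20.2, so the remaining markers did not share it, and a biological rise of macrophages around ILC1s in knockout liver was not tested.

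The third pattern is the fall of Gzmb and Gzmc in knockout, while Gzma (−0.29) did not pass and Gzmk had the opposite sign without passing (0.56, SE 0.27, 2.25 against 1.27 FPKM); the design gives the genotype as a biological explanation. Dilution of ILC1 RNA by cells that lack the ILC1 signature genes would lower this signature as much as Gzmb (−0.50). Its median was 0.0232, above the value of Gzmb by more than 0.236, its quartile deviation, which argues against such dilution. Among its members Gpr183 (1.08) and Tmem176b (0.45) rose, while Xcl1 (−0.34) and Tnfsf10 (−0.33) did not pass. Cells that share signature genes could hold the median up, so dilution by such cells stays open. A shift of scale by haemoglobin and mitochondrial RNA is too small to give this fall. Haemoglobin mRNAs made up 2.42% and 2.66% of summed FPKM in knockout and 4.78% and 5.15% in WT. Mitochondrial mRNAs made up 2.51% and 2.89% in knockout and 1.30% and 1.64% in WT. Without those genes Gzmb had −0.53 (limma adjusted p = 0.00481) and Gzmc −1.56, which such small shares fixed beforehand. The adjusted p of Gzmb ranged from 6.79e-04 to 0.329 over its alternatives, and it did not pass without WT replicate 1 or 3 (−0.50 in each case). A lower content of these 2 transcripts in knockout ILC1s and a change in the mix of ILC1 subsets both stay open, and neither was tested.

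For the count of 316 genes, 1 of the 3 splits of the 4 libraries, the real one, gave as many with limma, and the highest of the other 2 gave 0 (182 genes at an unadjusted p under 0.05, against 1468). Each of the other 2 splits puts 1 knockout and 1 WT library in each group. A difference between the genotypes then adds to the variance within groups and lowers the count, so their 0 does not measure chance. Limma's camera called 12 gene lists in the real split and 3 in the split that sets both libraries of replicate number 1 against the rest. With 3 splits a share under 0.05 cannot be reached.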
